A study of Mus musculus with 2 samples.

How the data were processed

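MicroRNA sequencing libraries had been made from total RNA of 2 single forebrains of B6NCrl mice on postnatal day 0, pup 1 and pup 3. The labels list a size limit of under 30 for the RNA, with no unit. Both pups carry the same donor entry in the labels, and the sex was not collected. The forebrains are separate animals and were taken as biological replicates.

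The authors deposited a table of raw read counts per miRNA gene for each library, with no normalization, and per the labels and the text deposited with the files the assembly is mm10 and the annotation release M4. The aligner, the counting tool and their versions are not given in the sources used here. Each deposited table has 3 columns of counts, for both strands together, for the strand of the gene, and for the opposite strand, as read from their layout and values. The column of the gene strand was used as planned, and held 97.6% of the counts of both strands in pup 1 and 98.1% in pup 3. The first 4 rows name no gene and were left out of library sizes. Reads that did not map made up 13.4% of the 6657203 reads of pup 1 and 12.3% of the 5883027 reads of pup 3. Reads that map to several places made up 42.2% and 44.1%, reads on the strand of no miRNA locus 3.23% and 2.27%, and ambiguous reads 0. With both strands counted, reads outside miRNA loci made up 2.21% and 1.48%. Counts on the gene strand of a locus were 41.2% of the reads in both pups. A miRNA made from several identical loci loses reads to the row of multiple mapping, so shares are shares of reads that map to 1 place. Ligation and amplification in small RNA libraries favour some sequences over others, so shares compare a locus between libraries better than loci with each other.

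Gene names, positions and hosts came from the GENCODE M21 annotation of GRCm38, the same assembly as mm10. Of the 1973 rows, 1894 matched by identifier, and the 79 others had at most 1 count. Some genes of the fixed lists had no row and are in no list share. Beyond those named with the let-7, Dlk1-Dio3, neural progenitor and white blood cell lists, they were Mir126b (blood vessel), Mir216c (liver, gut and pancreas), Mir1a-2 (muscle), Mir219b and Mir219c (oligodendrocyte), Mir290b and Mir292b (pluripotent), Mir451b (red blood cell), and Mir466b-1, Mir466c-1, Mir466e and Mir669a-4 to Mir669a-12 (rodent repeats). A host is a gene that is no miRNA and overlaps the locus on its strand. Hairpin sequences of the 1894 loci were compared with each other, and loci that share a run of at least 20 nt were marked.

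Shares are percents of gene-strand counts, and CPM are counts scaled to a total of 1e+06 of them. The mean and SD are over both pups. For a single library, exact Clopper-Pearson intervals at 95% were computed, and a count of 0 was given a floor of 3 counts. A locus was detected with at least 10 counts in both libraries. Log2 ratios are of CPM + 1 in pup 3 over pup 1. Loci with at least 10 summed counts were tested by Fisher's exact test against the rest of the library, two-sided, with Benjamini-Hochberg adjustment at 0.05. With a single group, edgeR's quasi-likelihood test has no contrast, so edgeR gave only the common dispersion of an intercept model. List medians were set against 10000 random lists, drawn from all rows for levels and from the 100 loci nearest in mean level to each member for ratios. Clusters are loci within 10 kb of the next on a strand. Random lists took no account of clusters, so list percentiles treat neighbouring loci as independent draws.

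Settings restricted to loci that share no run were added after the data were seen. The tests of explanations and of counts on the opposite strand were also chosen after the data were seen. The 18 lists, the other tests and the other alternatives were fixed before the data were examined. The rule for named loci, also fixed then, takes the 20 loci of the highest mean share, the 3 highest members of each list, and the 5 highest and 5 lowest log2 ratios among loci with at least 100 summed counts that passed the test. The tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16 and DESeq2 1.42.0.

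The test was checked on simulated counts with the library sizes and levels of these libraries. These counts held Poisson sampling noise only and no variation between animals. They do not show how many loci such variation alone would call. Of 68 loci changed by 1.5-fold 64.7% were recovered, of 66 changed by 2-fold 84.8%, and of 66 changed by 4-fold 92.4%, and of 406 loci with identical shares 0 were called. Simulated coefficients of variation of 0.1, 0.2 and 0.4 were estimated as 0.0965, 0.194 and 0.408. Alternatives were the unstranded column, leaving out the most abundant locus or a replicate, other filters, pseudocounts, scalings and cluster distances. In place of edgeR's common dispersion, the median of DESeq2's dispersions per locus was also taken.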

Results

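MicroRNAs, short RNAs cut from hairpin precursors that repress messenger RNAs, were sequenced from the forebrain of mice of strain B6NCrl on postnatal day 0. The series holds 1 group of 2 libraries. Replicate 1 was made from the single forebrain of pup 1 and replicate 2 from that of pup 3. No condition was compared, so the results are the level of each miRNA locus, its spread between the 2 animals (mean ± SD, n = 2 throughout), and the differences between these libraries. Reads on the strand of a miRNA locus totalled 2742746 in pup 1 and 2427066 in pup 3. The floor of 3 counts given to a count of 0 was 1.09 CPM (counts scaled to a common total of 1e+06) in pup 1 and 1.24 CPM in pup 3. Intervals and floors cover counting error only, since the labels name no molecular identifiers and PCR copies of a molecule count as separate reads. Coordinates refer to the mouse assembly GRCm38.

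A single locus, Mir99a, held over 25.4% of the counts in each pup, and members of the let-7 family, which act against proliferation and rise as neural tissue matures, came next. Mir99a (ENSMUSG00000065530.1, chromosome 16, 77598936 to 77599000, plus strand, within the host transcript Mir99ahg) held 26.9% ± 2.04 of the counts. Its share was 25.5% in pup 1 (95% exact Clopper-Pearson interval 25.4 to 25.5%) and 28.4% in pup 3 (28.3 to 28.4%). Mirlet7g (ENSMUSG00000065440.1, chromosome 9, 106178840 to 106178927, in an intron of Wdr82) held 6.63% ± 0.181, and Mirlet7i (ENSMUSG00000065406.2, chromosome 10, 122985640 to 122985724, with no host gene on its strand) held 4.08% ± 1.37. Mir126a, the miRNA of blood vessel endothelium, lies within Egfl7 on chromosome 2 (26591357 to 26591429) and held 3.30% ± 0.358. Mir100, which shares its seed with Mir99a, held 3.23% ± 0.366, and Mir99b, of the same family, held 2.18% ± 0.140.

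The neuronal Mir137 (chromosome 3, 118433857 to 118433929, in an exon of the noncoding transcript Gm26871) stood at rank 9 with 2.58% ± 0.350. Mir149, in an intron of Gpc1, held 2.64% ± 0.117. Mir487b, from the Dlk1-Dio3 imprinted region, held 2.63% ± 0.666, and Mir335, in an intron of the imprinted gene Mest, held 2.59% ± 0.575. The other 10 of the 20 most abundant loci were Mir130a (1.78% ± 0.0865), Mirlet7b (1.62% ± 0.383), Mir30e (1.56% ± 0.233), Mirlet7d (1.44% ± 0.220), Mir181c (1.21% ± 0.0554), Mir128-1 (1.10% ± 0.0405), Mir17 (1.02% ± 0.0294), Mir22 (0.995% ± 0.0482), Mir26b (0.960% ± 0.173) and Mir342 (0.956% ± 0.0989). Of the 20, 17 lay within an annotated host transcript on the same strand. Neighbouring ranks often lay closer than the spread between the pups: Mir149, Mir487b, Mir335 and Mir137 could not be ordered at n = 2.

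**Figure D1:**
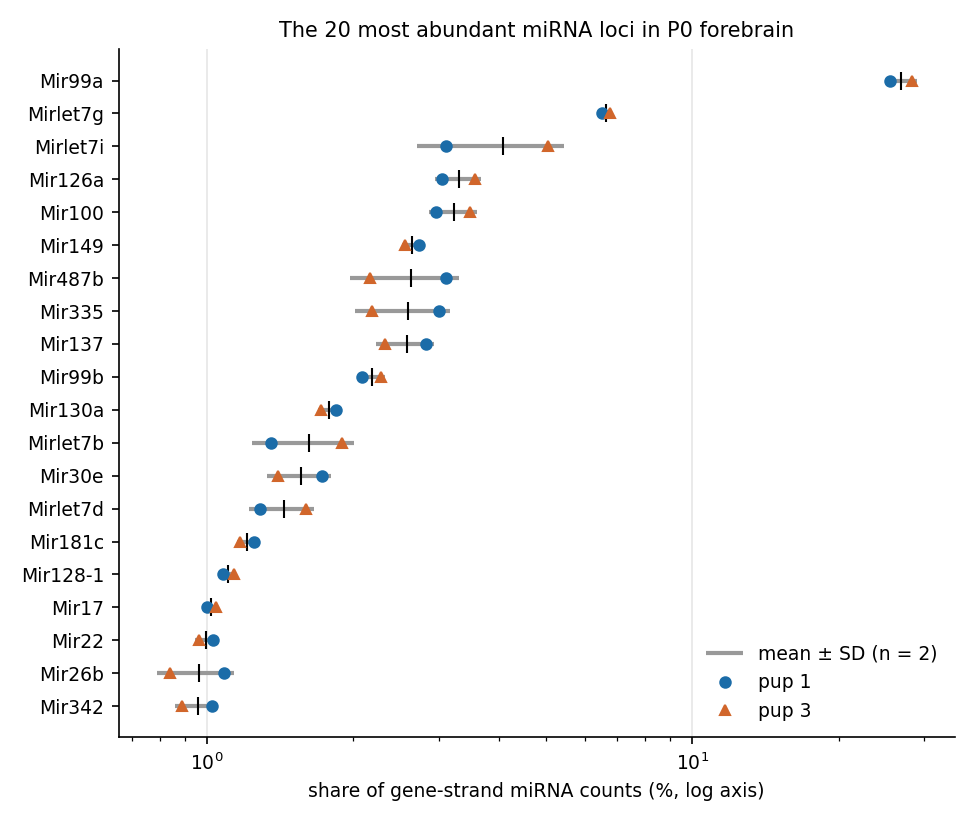
Share of gene-strand miRNA counts (percent, log axis) of the 20 most abundant loci, with pup 1 as circles, pup 3 as triangles, the mean as a tick and the SD as a grey bar (n = 2). Mir99a stood at 26.9%, and the loci below Mirlet7g lay between 0.956% and 4.08%.

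The counts assigned to loci were concentrated. Reads that map to several places are in none of these values, so the concentration of all miRNA reads is uncertain. By mean share, 8 loci held 50% of the counts, 65 held 90% and 170 held 99%. The 20 most abundant loci together held 69.5% ± 2.72. Of the 1973 rows, 331 loci (16.8%) had at least 10 counts in both pups, and 1303 had no count in either. Without Mir99a, 14 loci held 50%.

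Of the lists fixed before the data were examined, the let-7 family held the largest share. The let-7 family (10 of 10 loci detected) held 15.0% ± 2.40 of the counts, without Mirlet7e and Mirlet7f-1, to which no row matched. The neuron-enriched list held 4.87% ± 0.494, with 13 of 15 loci detected. It was led by Mir137, Mir128-1 and Mir128-2, the last at 0.408% ± 0.0319. The neural progenitor and pan-neural list held 0.916% ± 0.0491, from Mir125b-1 (0.336% ± 0.0388), Mir92b (0.289% ± 0.0928) and Mir125b-2 (0.237% ± 0.00466), without Mir9-1, to which no row matched, with 75.3 ± 26.6 CPM on the strand opposite Gm25641, where it lies. The miR-17-92 cluster and its paralogs, which are high in dividing cells, held 2.56% ± 0.0172, led by Mir17, Mir93 (0.480% ± 0.0320) and Mir106b (0.459% ± 0.0596). The median log2 CPM of every fixed list except the rodent repeats lay at or above the 94.5 percentile of 10000 random lists of the same size drawn from all rows. Most rows had no count, so this percentile does not set neural lists apart from others. Loci that share a run with another hairpin were 11 of 15 neuron-enriched, 4 of 5 neural progenitor and 5 of 10 let-7 loci. Their reads that map to several places are in no list share, so the order of these lists by share is uncertain.

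The other lists ranged widely in share. Blood vessel loci held 3.72% ± 0.313, most of it from Mir126a, with Mir143 at 4003 ± 431 CPM and Mir145a, both of smooth muscle, at 0.0123% ± 0.00178. Oligodendrocyte loci, which mark myelin-forming cells, held 0.0639% ± 0.0127, most of it from Mir338 (0.0512% ± 0.00868), with Mir219a-1 at 102 ± 35.5 CPM and Mir219a-2 at 25.5 ± 4.63 CPM. Microglia and other white blood cell loci held 0.0437% ± 0.00137, led by Mir150 (196 ± 17.2 CPM), Mir223 (145 ± 1.88 CPM) and Mir146 (185 counts in pup 1 and 79 in pup 3). This leaves out Mir142, which has no row, with 191 ± 18.0 CPM on the strand opposite Mir142b, where it lies. Red blood cell loci held 0.00798% ± 0.00120, with Mir451a at 44.1 ± 9.87 CPM, Mir144 at 22.3 ± 4.10 CPM and Mir486 at 13.4 ± 1.98 CPM. The liver, gut and pancreas list held 0.0306% ± 0.00431, led by Mir192 (115 ± 12.7 CPM), Mir194-2 (74.4 ± 18.5 CPM) and the liver miRNA Mir122 (55.6 ± 10.5 CPM). Hox cluster loci, which mark the hindbrain and spinal cord, held 0.0252% ± 0.00228, led by Mir10b (135 ± 21.8 CPM) and Mir10a (106 ± 2.64 CPM), with Mir615 at 5.75 ± 1.14 CPM.

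The epithelium list held 0.775% ± 0.399, led by Mir429 (0.409% ± 0.245), Mir200b (0.127% ± 0.0865) and Mir203 (0.123% in the mean of both). Multiciliated cell loci, typical of ependyma and choroid plexus in the brain, held 0.656% ± 0.231, from Mir449a (0.468% ± 0.176), Mir34c (0.180% ± 0.0519) and Mir34b (81.1 ± 26.6 CPM). The pituitary and neuroendocrine list held 0.391% ± 0.101, led by Mir7b (0.239% ± 0.0801), with Mir7-2 at 595 ± 73.3 CPM and Mir7-1 at 592 ± 98.2 CPM. Sensory organ loci held 0.151% ± 0.0894, from Mir182 (733 ± 407 CPM), Mir183 (534 ± 353 CPM) and Mir96 (246 ± 134 CPM). The pluripotent cell list held 0.00726% ± 0.00287, with 3 of 12 loci detected, Mir302a (28.4 ± 5.21 CPM), Mir302d (21.3 ± 12.1 CPM) and Mir302b (17.4 ± 8.89 CPM). The muscle list held 0.00399% ± 0.00182, led by Mir208b (25.8 ± 15.9 CPM), Mir206 (5.91 ± 1.95 CPM) and Mir1b (3.13 ± 0.817 CPM), and 4 of its 9 loci, Mir1a-1, Mir133a-1, Mir133a-2 and Mir133b, had no count in either pup. All 4 share a run with another hairpin, and reads that map to several places are counted at no locus. Their lack of counts therefore does not show that these miRNAs were absent. The rodent repeat families of the Sfmbt2 intron held 0.212% ± 0.0233, with 7 of 68 loci detected. Its leading loci were Mir467d at 0.0679% ± 0.00110, Mir467e at 0.0679% ± 0.0141 and Mir467c at 0.0353% ± 0.00661, all within that intron.

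**Figure D2:**
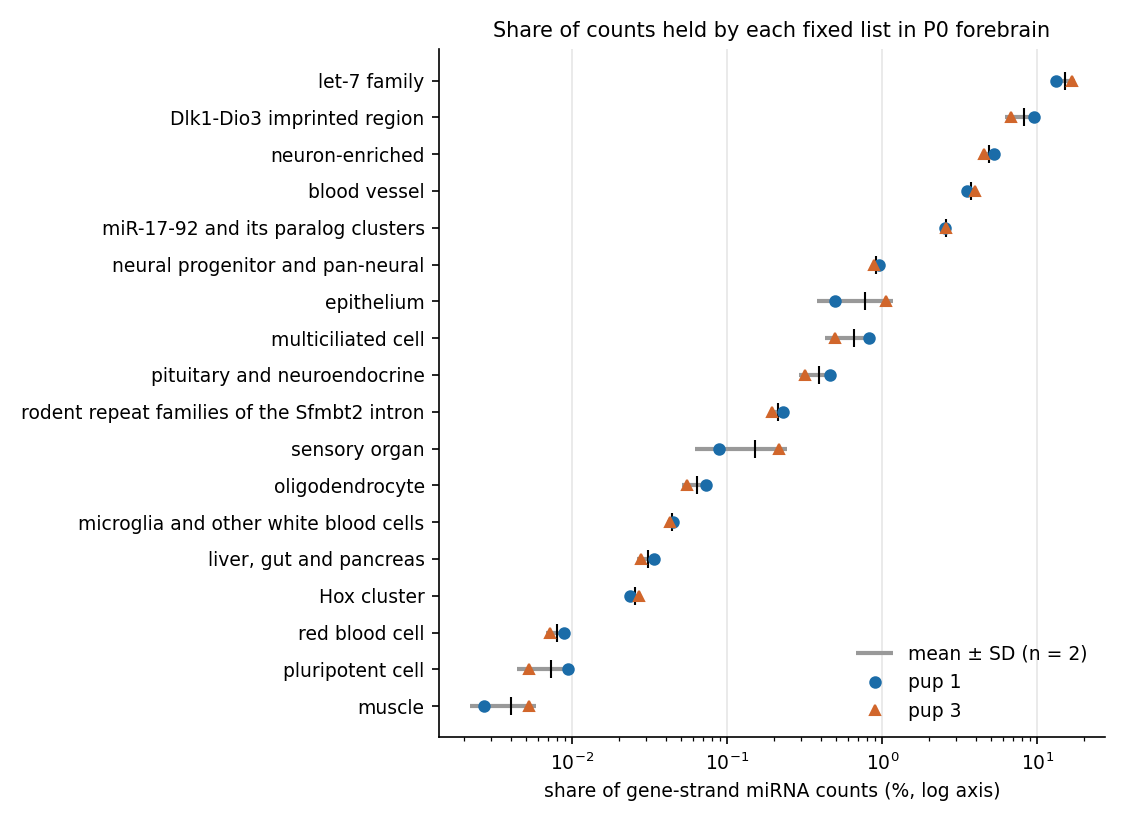
Share of gene-strand miRNA counts (percent, log axis) of the 18 fixed lists, with pup 1 as circles, pup 3 as triangles, the mean as a tick and the SD as a grey bar (n = 2). Shares ran from 15.0% for the let-7 family to 0.00399% for muscle, and the epithelium and sensory organ lists had wide bars, with pup 3 above pup 1.

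The Dlk1-Dio3 region, an imprinted stretch whose miRNAs are made from the maternal chromosome, was the second most abundant list. Its 50 loci held 8.20% ± 1.98 of the counts, with 44 detected, and without Mir136, Mir299a, Mir376a, Mir376b, Mir380 and Mir409, to which no row matched. On chromosome 12, 49 of them spanned 184 kb, from 109563692 to 109747960, and 47 lay on the plus strand. Levels of detected members ran from 10.4 to 26346 CPM. Mir487b led (chromosome 12, 109727333 to 109727414), followed by Mir369, in the host transcript Mirg, with 7325 ± 1280 CPM, and Mir127, with 7299 ± 2440 CPM.

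**Figure D3:**
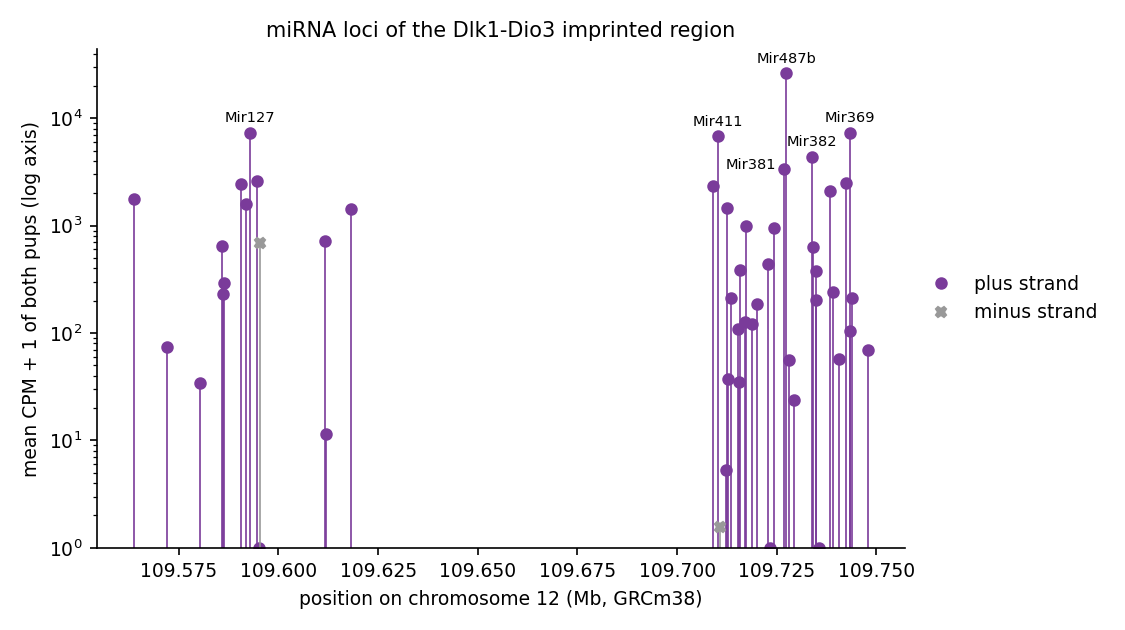
Mean CPM + 1 of both pups (log axis) at each miRNA locus of the Dlk1-Dio3 list against its position on chromosome 12 (Mb), with circles for the plus strand and crosses for the minus strand. Mir487b stood highest at 26346 CPM, and loci a few kilobases apart differed by orders of magnitude.

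Loci that lie close together on a strand differed widely in level. Loci within 10 kb of the next on their strand formed 104 clusters, of which 42 had at least 2 detected loci. These 42 held 59.99% of the counts. The highest and the lowest detected locus of a cluster differed by 17.1-fold in the median (4.09 on the log2 scale), and by over 10-fold in 24 clusters. In some clusters the lowest locus shares a run with another hairpin, so its reads that map to several places are not counted. Of loci named after their values were seen, Mir30c-1 (396-fold below the highest) and Mir181b-1 (1098-fold) share a run, and Mir449c (906-fold) does not. Folds set by a locus that shares a run may overstate the difference in level. On chromosome 14, Mir17 stood 1363-fold above Mir19b-1, whose hairpin shares a run with that of Mir19b-2. Mir221 and Mir222 on the X chromosome, named after their values were seen, differed by 1.24-fold.

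Numbered copies lay close in level in some miRNAs and far apart in others. Mir7-2 and Mir7-1 had 595 ± 73.3 and 592 ± 98.2 CPM, and Mir125b-1 and Mir125b-2 had 3363 ± 388 and 2371 ± 46.6 CPM. Mir128-1 and Mir128-2 had 11051 ± 405 and 4084 ± 319 CPM, while the 3 loci of the neuronal miR-124 had 7.06 ± 2.25 CPM (Mir124a-1), 1.74 ± 0.124 CPM (Mir124a-2) and 0.959 ± 0.191 CPM (Mir124a-3). Mir9-2 had 1.87 ± 1.48 CPM, and Mir26a-1 and Mir26a-2 had 12.3 ± 1.67 and 43.0 ± 1.53 CPM, against 9605 ± 1732 CPM at Mir26b. The miR-124, Mir9-2, Mir26a and Mir19b-1 loci were named after their values were seen. Reads that map to several places, of which the libraries held 1.02 (pup 1) and 1.07 (pup 3) per assigned count, are in no locus, so levels of miRNAs with copies are uncertain. Of 713 loci that share a run of at least 20 nt with another hairpin in both parts of their own, 2.24% were detected, against 26.5% of 965 loci that share none. Of 216 loci that share a run in 1 part, 27.3% were detected, and these held 10.4% ± 0.585 of the counts.

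The levels of the 2 pups ran closely together across loci. Over the 1973 rows, Pearson's r of log2(CPM + 1) was 0.995 and Spearman's rho 0.901, and over the 331 detected loci they were 0.991 and 0.990. Loci are not independent replicates, so no p-value was computed. The biological coefficient of variation, from edgeR's common dispersion, was 0.251. A different measure, the square root of the median of DESeq2's dispersions per locus, was 0.148. The libraries differed beyond sampling noise (chi-square 209 per degree of freedom over 331 loci), so they are not copies of 1 library, and both were kept. The median log2 ratio of pup 3 over pup 1, over 400 loci with at least 10 summed counts, was −0.31, and 83.1% of detected loci lay within 1.5-fold of it. With DESeq2 size factors the median of detected loci was −0.00, so directions below are also given relative to the median.

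The 2 libraries differed at many loci. Each side is 1 pup, so Fisher's exact test (two-sided, Benjamini-Hochberg adjusted over the 400 loci) compares these libraries, not conditions. It called 226 loci, 41 higher and 185 lower in pup 3. With TMM-adjusted library sizes, 82 were higher and 104 lower, and with DESeq2 size factors 98 and 83. By 2-fold or more, 27 loci differed with totals as the scale, and 17 with either of the other scales. Of the 20 most abundant loci, 10 were higher and 10 lower in pup 3 relative to library totals. With size factors, 6 of the 10 lower ones were higher, 3 were lower (Mir487b, Mir335 and Mir26b), and Mir30e did not pass, at a log2 ratio of 0.01.

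The 5 miR-200 family loci of the epithelium list and the 3 sensory organ loci were more than 2-fold higher in pup 3. In the epithelium list, 5 of 7 loci were higher and none lower, and 6 were higher with size factors. Mir200b had a log2 ratio of 1.51, Mir429 1.30, and Mir200a 1.41 (adjusted Fisher's exact p = 1.02e-78). The other 2 loci of the list did not pass with library totals: Mir203 had 0.00 and Mir205 −0.38. With size factors Mir203 passed, at 0.31 (adjusted exact binomial p = 3.83e-17), and Mir205 had −0.08. All 3 loci of the sensory organ list, Mir183, Mir182 and Mir96, were higher, with log2 ratios of 1.46, 1.20 and 1.17. The list medians, 1.28 and 1.20, lay at the 100 and 99.8 percentile of 10000 random lists matched on level. Mir429, Mir200a and Mir200b lie in the same cluster, as do Mir141 and Mir200c, and as do the sensory organ loci. The random lists were drawn locus by locus, so these percentiles overstate the number of independent loci. The epithelium list held 0.493% of the counts of pup 1 (95% exact interval 0.485 to 0.501%) and 1.06% of those of pup 3 (1.04 to 1.07%). Mir208b, of the slow heavy chain gene Myh7, was also among the 5 highest ratios, at 1.29 from 40 and 90 counts.

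All 10 let-7 loci with a row were higher in pup 3, under library totals and under size factors alike. Mirlet7e has no row, and the counts opposite Gm25927, where it lies, did not differ with totals (12575 and 11132 counts, log2 ratio 0.00), while with size factors they were higher, at 0.31 (exact binomial test over 13 such loci, chosen after the values were seen, adjusted p = 1.35e-61). Those opposite Gm24111, where Mirlet7f-1 lies, were higher on either scale (370 and 608 counts, 0.89 with totals). The median log2 ratio of the 10 loci was 0.39, or 0.71 above the median of all tested loci, at the 100 percentile of matched lists, and Mirlet7i reached 0.70. Of 45 tested Dlk1-Dio3 loci, 36 were lower, none higher and 9 did not pass, with a list median of −0.54 (0 percentile). Many of these loci lie in shared clusters, which the random lists did not take into account. Adjusted over the list alone, 37 were lower. With size factors 29 were lower and 3 higher. Mir127 had a log2 ratio of −0.69. Multiciliated loci had a median of −0.67 at the 3.47 percentile, with 3 of 5 tested loci lower (Mir449a −0.79, Mir34c −0.60, Mir34b −0.67) and lower with size factors as well.

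**Figure D4:**
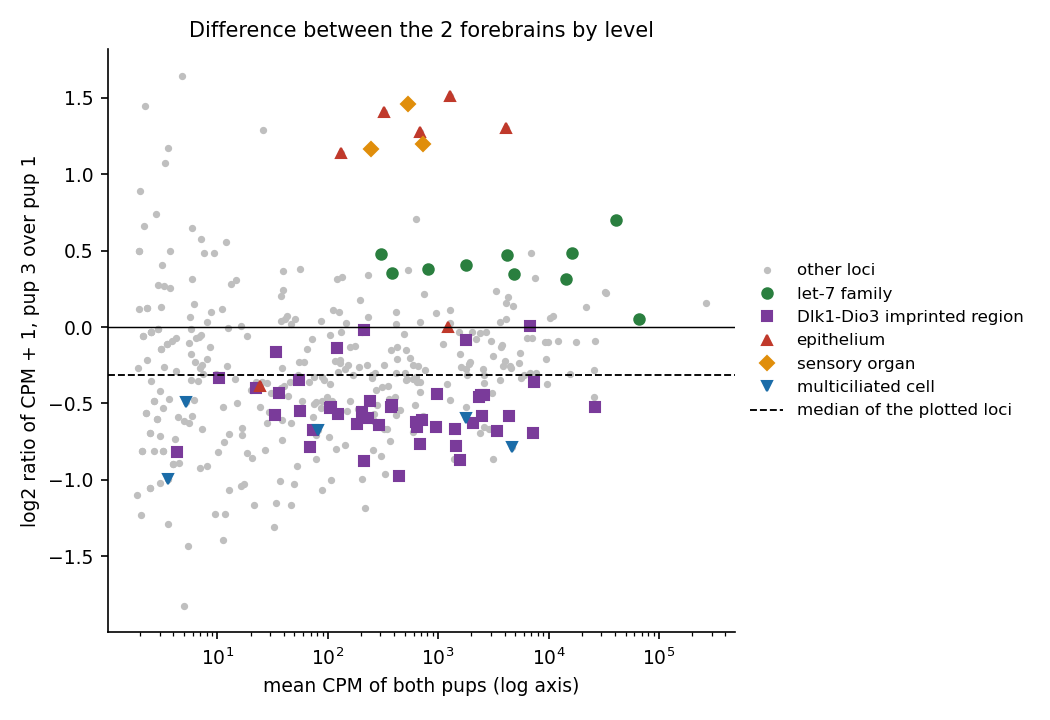
Log2 ratio of CPM + 1 in pup 3 over pup 1 against the mean CPM of both pups (log axis) for the 400 loci with at least 10 summed counts, with 5 fixed lists coloured. The dashed line is the median, −0.31, and the let-7 loci lay above it, most Dlk1-Dio3 loci below it, and 5 epithelium and 3 sensory organ loci above 1.

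Calls in the remaining lists often depended on the scale. Of 13 tested neuron-enriched loci, 2 were higher and 9 lower relative to library totals, but 4 higher and 5 lower with size factors. The neural progenitor list had 2 of 5 higher and 1 lower, Mir92b, with a log2 ratio of −0.67, and 3 higher and 1 lower with size factors. The miR-17-92 list had 4 of 13 higher and 2 lower, and with size factors 7 higher and none lower. The 4 pituitary loci were all lower relative to totals, but only Mir7b (−0.70) was lower with size factors. Blood vessel loci had 1 of 3 higher, Mir126a (0.22), and 2 lower, Mir143 and Mir145a, but 2 higher and none lower with size factors. Among 3 tested pluripotent loci, Mir302d (−1.17) and Mir302b (−1.03) were lower, with size factors too. Oligodendrocyte loci had 2 of 3 lower, white blood cell loci 1 of 4 lower (Mir146, −1.03), red blood cell loci 1 of 3 lower (0 adjusted over the list alone), and rodent repeat loci 4 of 10 lower. Hox cluster loci had 2 of 4 higher, with Mir10b at 0.33 and a list median of 0.16 at the 98.3 percentile (96.9 over its members with at least 10 summed counts). Liver, gut and pancreas loci had 1 of 6 higher and 3 lower, and muscle loci 1 of 5 higher. With size factors, rodent repeat loci had 2 higher and none lower, white blood cell loci 2 higher and 1 lower, oligodendrocyte loci 1 lower, red blood cell loci none of either, Hox cluster and muscle loci 2 higher each, and liver, gut and pancreas loci 1 higher and none lower. Adjusted over the list alone, the counts of every list other than Dlk1-Dio3 and red blood cell were the same. Among loci with at least 100 summed counts that passed the test, the lowest ratios belonged to Mir1224 (−1.31), Mir760 (−1.18), Mir7689 (−1.17), Mir302d and Mir6236 (−1.15).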

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

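All tests of explanations in this part were chosen after the result was seen. Counts on the strand opposite to the annotated locus are in no list share or list count of the report, and enter the list shares only under the alternative of the unstranded column. Of all loci, 13 had at least 10 of them in both pups, above the floor of 3 counts given to a 0. Summed over both pups, the opposite strand held 26155 counts at Gm25252, 23707 at Gm25927, 20335 at Gm24321, 19762 at Gm24083, 8576 at Gm25301, 5940 at Mir497b and 3976 at Gm25750. It held 2747 at Mir299b, 990 at Mir142b, 978 at Gm24111, 395 at Gm25641, and 69 each at Mir203 and Mir3074-1.

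Reads counted on the wrong strand across the library are argued against. At rows whose other strand holds no miRNA gene without a row of its own, there were 0.0308 opposite counts per 1000 gene-strand counts. A candidate explanation is that these are reads of miRNA genes on the other strand that have no row in the tables. In the later annotation, 99.9% of the opposite counts lay at rows overlapping such a gene, among them Mir376a opposite Gm25252, Mirlet7e opposite Gm25927, Mir409 opposite Gm24321, Mir191 opposite Gm24083 and Mir378a opposite Gm25301. On this reading Mirlet7e stood at 4586 ± 1.26 CPM and Mir376a at 4977 ± 1914 CPM, levels that the shares of the let-7 and Dlk1-Dio3 lists leave out, as they do those of Mirlet7f-1, Mir299a, Mir380 and Mir409. No biological explanation was tested, and the 69 counts at Mir203, which has no such gene, stay open.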

How the results depend on the processing

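Shares restricted to loci that share no run, and cluster ranges so restricted, were added after the data were seen. Leaving out a replicate leaves the other pup's value, which by construction lies within 1 SD of a mean of 2. No paired analysis was possible because there is 1 group. The next setting adds the reads that map to several places to the total alone and to no list. It therefore cannot show the share a list would have with its own such reads. With reads that map to several places in the total, shares fell for every list but epithelium and sensory organ by more than 1 SD, as the larger total requires: Mir99a 13.2%, neuron-enriched 2.38%, neural progenitor 0.448%, let-7 7.32%, miR-17-92 1.25%, oligodendrocyte 0.0313%, white blood cell 0.0213%, red blood cell 0.00390%, vessel 1.81%, muscle 0.00194%, liver and gut 0.0150%, multiciliated 0.321%, pituitary 0.191%, pluripotent 0.00356%, Hox 0.0123%, Dlk1-Dio3 4.01% and rodent repeat 0.103%. Without Mir99a, shares rose by construction: neuron-enriched 6.66%, neural progenitor 1.25%, let-7 20.6%, miR-17-92 3.51%, oligodendrocyte 0.0873%, white blood cell 0.0597%, red blood cell 0.0109%, vessel 5.10%, liver and gut 0.0418%, multiciliated 0.894%, pituitary 0.533%, Hox 0.0345%, Dlk1-Dio3 11.2% and rodent repeat 0.289%, and 14 loci held 50% of counts. Over members that share no run, shares were 3.10% for neuron-enriched, 0.289% for neural progenitor, 2.43% for miR-17-92, 0.0512% for oligodendrocyte, 0.0387% for white blood cell, 0.0231% for liver and gut, 0.272% for pituitary, 0.00263% for pluripotent, 4.83% for Dlk1-Dio3 and 0 for rodent repeat. With the unstranded column, miR-17-92 held 2.51% and white blood cell 0.0614%, the latter from opposite-strand counts at the row of Mir142b, where Mir142 has no row. With at least 1 count in both pups, 527 loci were detected. Pearson's r was 0.993 and 0.996 with pseudocounts of 0.5 and 10 CPM, and over detected loci r was 0.991 and rho 0.990. The coefficient of variation was 0.215 with TMM and 0.216 with size factors. The value of 0.148 with DESeq2 is from the median dispersion per locus, a different measure from edgeR's common dispersion. The split of loci higher and lower in pup 3 depended on the scale: 41 and 185 with totals (18.1% higher), 82 and 104 with TMM (44.1%), 98 and 83 with size factors (54.1%), with 17 loci past 2-fold under either. Among loci that share no run, a setting added after the data were seen, 25 were higher and 156 lower with totals (13.8% higher). List percentiles entered or left the outer 2.5% on either side for muscle (99.99 over members with at least 10 summed counts), multiciliated (0.940 with a pseudocount of 10 CPM), pluripotent (1.25 with TMM, 0.920 with size factors, 0.740 with a pseudocount of 0.5 CPM, 2.44 over members with at least 10 summed counts) and Hox (96.9 over such members). The cause of these crossings was not tested. For single named loci, 118 settings moved the share by over 1 SD and 302 did not. Other settings moved counts of loci by at most 1.5 times, the tolerance set for counts, among them 239 loci detected with at least 100 counts in both pups and 18 past 2-fold with at least 100 summed counts. They moved list shares by less than 1 SD and kept list percentiles on their side of the outer 2.5%. Depth limits the muscle, red blood cell and pluripotent lists, whose loci had 11 to 140 counts where detected.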

Other observations

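The tests of explanations in this part were all chosen after the results were seen, as were the loci of the next sentences. The 3 places in the genome where a member of the miR-99 and miR-100 family is followed by a let-7 or miR-125 locus held 27.0% ± 2.06 (Mir99a and Mirlet7c-1, chromosome 16), 3.26% ± 0.373 (Mir100 and Mirlet7a-2, chromosome 9) and 2.89% ± 0.114 (Mir99b and Mir125a, chromosome 17) of the counts (SD, n = 2). The first member stood above the other by 331-fold, 105-fold and 3.09-fold. Mirlet7c-1 and Mirlet7a-2 share runs with other hairpins and Mir125a does not. Mirlet7e, on chromosome 17 between Mir99b and Mir125a, has no row and is left out of these values.

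The 5 loci of the miR-200 family (Mir200a, Mir200b, Mir200c, Mir141, Mir429) and the 3 of the miR-183 cluster (Mir96, Mir182, Mir183) held 0.456% of the counts of pup 1 and 1.15% of those of pup 3, and their folds lay between 2.22 and 2.86. Counting noise is argued against, since the lowest lower bound of the 8 folds (95% exact interval) was 1.89. The lowest log2 ratio under TMM and size factors was 1.39, so the 8 loci were higher on these scales as well as with totals. Both scales raise the ratios of pup 3 above those with totals, so this could not have gone against the pattern. Mir203 and Mir205 had a mean log2 ratio of −0.19 (0.12 with size factors, where Mir203 was higher at 0.31). They are the 2 loci of the epithelium list that were set apart from the miR-200 family after their values were seen. They therefore cannot decide whether pup 3 held more skin or mouth epithelium. More pituitary or other neuroendocrine tissue is argued against by its 4 loci, with a median of −0.30 (0.02 with size factors). On either scale the values of both sets lay below those of the 8 loci, whose lowest ratio was 1.14 with totals. The highest ratio among the 4 pituitary loci was −0.25 (0.06 with size factors). The pituitary values argue against tissue that would raise those loci, not against an amount too small to change them. What stays open, and was not tested, is that the 2 dissections held different amounts of another epithelial or sensory tissue for which no list was fixed, or that the animals differed. More skin or mouth epithelium in pup 3 also stays open. With 1 pup on each side these cannot be resolved, and the pattern is a hypothesis from 2 libraries.

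Of loci whose hairpin shares a run with another hairpin in both parts, 2.24% were detected, against 27.3% of those that share it in 1 part and 26.5% of those that share none, and these differences were not tested. A candidate explanation for low counts at copies is that reads that map to several places are counted at no locus. Within 14 miRNA numbers that have loci of both kinds, the loci that share a run were lower in 11, with a median log2 difference of −2.06, but the two-sided exact sign test gave p = 0.0574. Mir28, Mir302 and Mir669 went the other way. So these 14 numbers cannot tell how much of the low counts comes from this loss and how much from lower expression. Neither miR-124 nor miR-9 is among the 14. Reads that map to several places are counted at no locus, so a low count at a copy does not by itself show low expression. No biological explanation was tested.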
